A study of Arabidopsis thaliana with 4 samples.

How the data were processed

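RNA from whole max3 seedlings treated with GR24 or with solvent was measured on single-channel oligonucleotide arrays, 2 per treatment. The deposited values are on the log2 scale and were made by RMA, per the submitters' processing notes, with no version given in the sources used here. RMA corrects the background, equalises the distributions between arrays and combines the probes of a set, and the 4 arrays had nearly equal quartiles. Differences between dim probe sets after RMA can be noisy, and an offset that compresses them was among the alternatives. The table held 22810 probe sets. Of these, 64 control probe sets were left out and 22746 were tested with no filter on dim signals.

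Gene names came from a table of the platform's probe sets, with symbols updated through gene identifiers or locus names. It listed 14016 of the tested probe sets, 13513 with 1 gene and 503 with several, and 8730 were not listed and are given here by probe set only. The named part is uneven, since it covers 63.3% of protein-coding genes known only by a locus name and 14.6% of those with a symbol of their own. For this reason 43 of the 407 genes in the fixed lists had a named probe set, and 10 of the 28 lists had no such member. A list gene is called measured here only where a named probe set stood for it. The other list genes may lie among the probe sets without 1 gene name, so they were not shown to be absent or unchanged.

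Differential expression was tested in R 4.3.3 with limma 3.58.1, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The design fixed before the data were examined compared the groups without pairing (2 residual degrees of freedom), with the replicate number as a block as an alternative (1 residual degree of freedom). Per the labels, both treatments carry replicate numbers 1 and 2, and the series description gives 2 independent analyses that each began with their own seedlings. The shared number was read as the shared preparation. A difference between preparations is thus one between replicate numbers, and array processing that went with the number cannot be told apart from the seedlings. Deviations from the group mean of same-numbered arrays correlated across probe sets at 0.712. Same-numbered arrays correlated at 0.996 and 0.997, against 0.989 for the mock pair and 0.993 for the GR24 pair. The median residual SD was 0.137 without the block and 0.0771 with it. Part of this drop arises because a median SD is lower on 1 than on 2 residual degrees of freedom. Where nothing separates the cultures within a preparation, p-values measure the spread between these arrays only. A random block could not be fitted. Other settings tried were repeated quantile normalization, median centring, leaving out dim probe sets, trend and robust moderation, an offset of 16, array weights, each array left out, a looser threshold of 0.1, a 1.5-fold criterion and 1 probe set per gene.

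The tests were first run on simulated data, 20 draws over 22746 probe sets with 200 changed ones each and the measured difference between preparations. The unpaired fit recovered 0% of changes of either size. With limma's default prior, which estimated 18.3 prior degrees of freedom in the real paired fit, 12.3% of calls were false. The prior variance was also refitted by maximum likelihood of the scaled F distribution of residual variances. This gave 7.62 prior degrees of freedom and a prior SD of 0.107. With the refitted prior 4.78% of calls were false, 15.4% of log2 changes of 0.5 and 98.2% of log2 changes of 1 were recovered. The simulated variances were drawn from the refitted prior, so a share of false calls near the threshold was built in and does not test that prior. Both the refitted prior and its use for naming changed genes were chosen after the data and the planned counts had been seen.

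Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 11 lists with at least 2 measured members, with 1 probe set per gene, the brightest on average. An estimated correlation and fry were alternatives. All these group tests, those of plastid genes and families included, used limma's own variance moderation and not the refitted prior. With an estimated correlation camera works on the residual degrees of freedom, 2 unpaired and 1 paired. It therefore has little power, above all in the paired design. In 50 simulated draws of the paired design, camera found the list of 10 genes shifted by 0.3 each time, and called 2 of 500 unshifted lists. Each gene had independent noise in these draws. False calls from correlated genes, in smaller lists or in the unpaired design were therefore not examined. The rule for named genes was fixed before the data were examined. It took up to 15 rises and 15 falls past the threshold with 1 gene name and the same sign in both pairs. It filled a direction with under 10 such calls to 10 by smallest unadjusted p, again among those with the same sign in both pairs. It also took every measured strigolactone gene, and up to 4 members of each other list. As the unpaired fit made no call, its first part was applied to the paired fit, and of list members those past 0.05 over the list alone are given with values. Of probe sets with no gene name, 2 per direction are given by identifier.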

Results

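Transcript levels were measured on 4 single-channel oligonucleotide arrays hybridised with RNA from whole 14-day-old Arabidopsis seedlings in the Col background. All seedlings carried the max3 mutation, which removes a carotenoid cleavage dioxygenase needed to make strigolactones, a class of plant hormones that restrain shoot branching. Seedlings of 2 arrays had been exposed for 90 min to 1 µM GR24, a synthetic strigolactone, and those of the other 2 arrays to the solvent dimethyl sulfoxide as a mock treatment. The median log2 value per array lay between 7.03 and 7.06, and the number of arrays, 2 per group, limits the precision of every value. The level of the mutated gene itself, MAX3, is not analysed here, because no probe set carried its name in the tables used.

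The comparison of GR24 with mock asked whether added strigolactone alters transcript levels in a mutant that cannot make its own. RR16, a type-A response regulator of cytokinin signalling, rose from a mean log2 value of 5.89 to 7.55. That was 3.16-fold (log2 change 1.66 ± 0.12, moderated SE, n = 2 pairs, adjusted p = 0.00161 in the paired limma model). AT1G64380, an AP2/ERF transcription factor, rose 3.02-fold (1.60 ± 0.10, adjusted p = 0.00161), and AT3G60290, a 2-oxoglutarate-dependent oxygenase, rose 2.63-fold (1.39 ± 0.11, adjusted p = 0.00371). Among the genes that fell were AT3G50340 (log2 change -1.29 ± 0.14, adjusted p = 0.00827) and the auxin-induced SAUR gene AT2G18010, also called SAUR10 (-1.22 ± 0.12, adjusted p = 0.00766). SAUR10 was dim with GR24 (mean log2 value 3.96), and its change was -0.73 with no call (adjusted p = 0.0776) when 16 was added to the linear values. These adjusted p-values come from limma's linear model with the replicate number as a block, in which the prior variance was fitted by maximum likelihood. Every value after ± in this report is a moderated SE from that model. With 7.62 prior and 1 residual degrees of freedom, it rests mostly on the prior variance shared by all probe sets. It therefore says little about the spread of a gene's own 2 pairs.

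In that paired fit 33 probe sets rose and 36 fell, and 69 passed the threshold among 22746 tested. The fit without pairing, which was the one set before the data were examined, called 0 probe sets in limma. In it 351 had an unadjusted p under 0.05, a share below 0.05 of those tested, against 1700 in the paired fit. On simulated data with the measured difference between preparations, the unpaired fit recovered 0% of log2 changes of 0.5 or 1. Its count of 0 therefore says little about whether GR24 acts. The planned paired fit with limma's default prior called 281, of which 136 were higher and 145 lower with GR24. On simulated data the default prior gave 12.3% false calls against 4.78% for the likelihood prior. Those data were drawn with the likelihood prior, so the comparison favours it and does not decide between the priors. As the stricter choice, the verbs rose and fell are kept for the 69 probe sets, all of which were also among the 281. The likelihood prior was chosen after the count of 281 and the simulation had been seen.

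**Figure D1:**
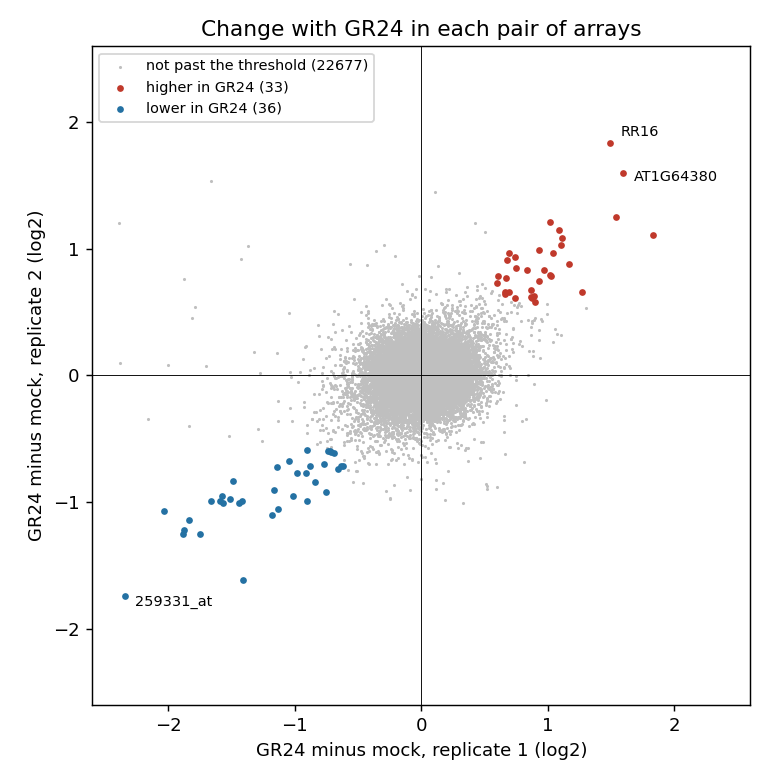
Each point is 1 of the 22746 probe sets, placed by its GR24 minus mock difference (log2) in the replicate 1 arrays on the x axis and in the replicate 2 arrays on the y axis. The 33 red probe sets passed the paired test as higher with GR24 and the 36 blue ones as lower. RR16 lies at 1.49 and 1.83, and the unnamed probe set 259331_at at -2.34 and -1.74.

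Of the 69 probe sets, 24 had 1 gene name, 15 of them higher and 9 lower with GR24. Other named risers were AT5G07580, another AP2/ERF factor (0.72 ± 0.10), the Dof factors AT2G34140 (1.00 ± 0.10) and AT1G29160 (0.80 ± 0.10), and the GRAS gene AT3G50650 (0.74 ± 0.11). AT5G53420, which encodes a CCT motif protein, rose 2.14-fold. The acyltransferase gene AT5G02890 rose by 0.90 ± 0.10, the protein kinase gene AT2G36350 by 0.65 ± 0.10 and the cytochrome P450 gene CYP71B22 by 0.66 ± 0.10. AT4G37240 (1.03 ± 0.11), AT3G16330 (0.96 ± 0.10), AT5G64550 (0.84 ± 0.11) and AT5G53710 (0.68 ± 0.10) completed the named risers. The calls of AT3G50650, AT5G53710, CYP71B22 and AT2G36350 ended with repeated quantile normalization (adjusted p from 0.0604 to 0.0694). With 16 added to the linear values the change of AT5G53710 was 0.44.

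Only 9 of the 36 probe sets that fell had a gene name, so their functions as a group are not known. The zinc-binding dehydrogenase gene AT5G16980 fell by 0.95 ± 0.10 on the log2 scale and the bHLH factor AT5G50915 by 0.80 ± 0.10. AT5G15950, which encodes an S-adenosylmethionine decarboxylase of polyamine synthesis, changed by -0.67 ± 0.10 and AT4G25780, a CAP superfamily gene, by -0.67 ± 0.10. AT3G42800 (-0.93 ± 0.12), AT5G12050 (-0.86 ± 0.12) and AT1G73120 (-0.74 ± 0.11) were the others. The calls of AT1G73120, AT4G25780 and AT5G15950 ended with repeated quantile normalization (adjusted p from 0.0531 to 0.0601). The 24 named genes had adjusted p between 0.00161 and 0.0477 in the paired fit and an adjusted p of 1 in the unpaired fit. Each moved the same way in both pairs, which the rule for naming genes required.

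The larger falls lay in probe sets with no gene name in the tables used. These numbered 45 of the 69, 18 higher and 27 lower with GR24. Probe set 259331_at fell by 2.04 ± 0.14 on the log2 scale, which left it 4.11-fold lower, and 259785_at fell by 1.51 ± 0.11. Among risers without a name, 262552_at rose by 1.47 ± 0.16 and 248964_at by 0.91 ± 0.11. Among probe sets with the same sign in both pairs, the 10 with the smallest unadjusted p in the unpaired fit were taken in each direction. All 20 passed the paired fit, which uses the same arrays and the same changes, so this is no independent check. Of the 20, 13 (4 higher and 9 lower) had no gene name.

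Expression also differed between the pairs of arrays. With treatment held constant, 3805 probe sets differed between replicate 1 and replicate 2, here called preparations, and 10 of the 24 named genes were among them. Seedlings and any array processing that went with the replicate number cannot be separated in this contrast. AT3G60290 was lower in preparation 2 by a log2 difference of -1.0 ± 0.11 (SE, n = 2 pairs), RR16 by -0.56 ± 0.12, CYP71B22 by -0.65 ± 0.10 and AT5G53420 by -0.47 ± 0.10. AT5G16980 was higher in preparation 2 by 1.09 ± 0.10 and AT5G15950 by 0.81 ± 0.10. In the fit without pairing, leaving out single arrays moved the change of 5 named genes by over 1.5 times, with no change of sign. Without GR24 replicate 1 the change of AT3G60290 was 0.82 and without GR24 replicate 2 it was 1.97. The others, between the fits without mock replicate 1 and without mock replicate 2, ranged from 0.30 to 1.02 for CYP71B22, from -1.52 to -0.38 for AT5G16980, from -1.21 to -0.51 for AT5G12050 and from -1.10 to -0.24 for AT5G15950. Without the probe sets that differed between preparations, 42 of the 69 calls were still tested and 41 of them passed. Only the prior and the adjustment can change in that setting, so it is no check of the calls against the preparation difference. Adding 16 to the linear values before taking log2 lowered the count to 24 and kept 8 of the 24 named genes past the threshold, RR16, AT1G64380 and AT3G60290 among them but none of the named genes that fell. Those 9 had changes from -1.24 for AT3G50340 to -0.60 for AT5G15950 on that scale, with adjusted p from 0.056 to 0.108.

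**Figure D2:**
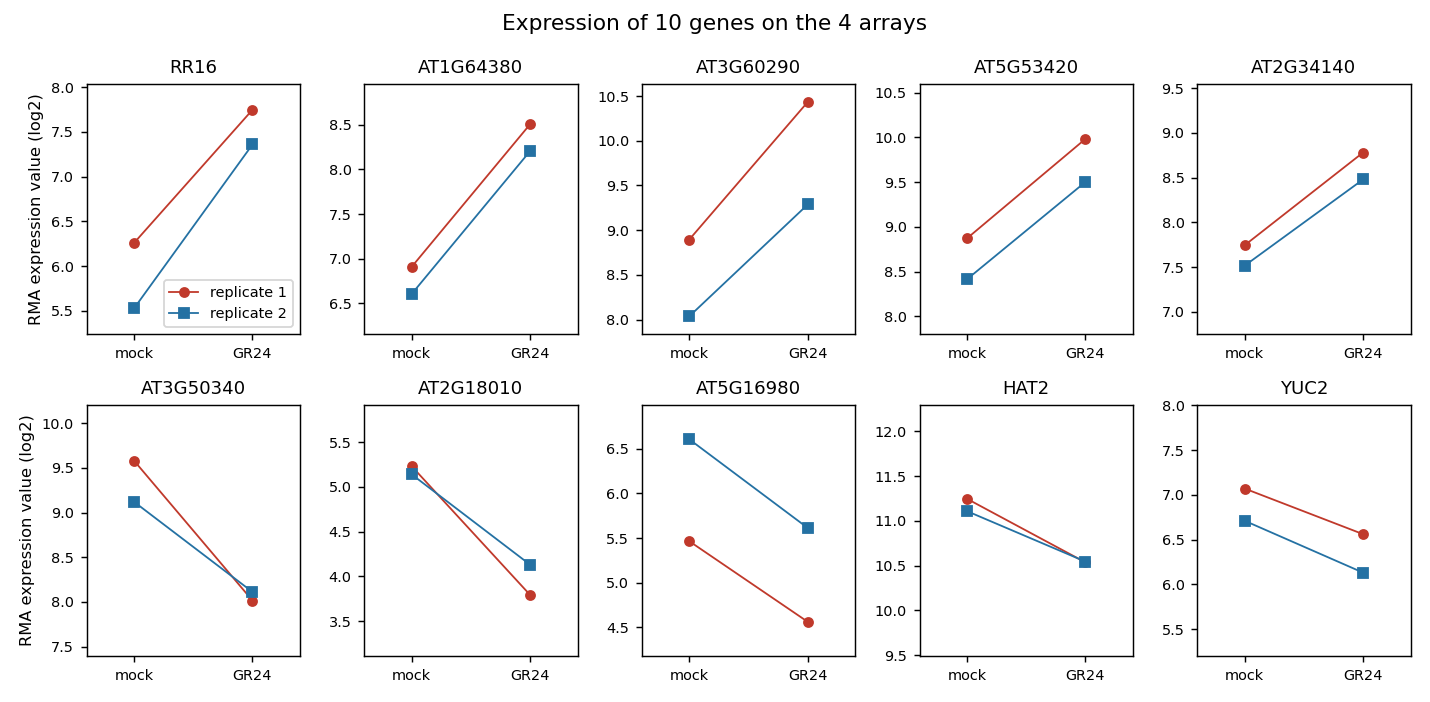
Expression (RMA value, log2) of 10 genes in mock and GR24 seedlings, with 1 point per array and a line joining the arrays of 1 replicate number. The y axes differ in level and share the same span. The top row holds 5 genes that rose, and in the bottom row AT3G50340, AT2G18010 and AT5G16980 fell, while HAT2 (-0.64) and YUC2 (-0.54) did not pass the paired test over all probe sets.

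Gene lists fixed before the data were examined were tested as groups. The early auxin response list shifted down over the 10 of its 35 members that had a named probe set. The mean log2 change was -0.21 and the median -0.06 (limma camera, adjusted p = 0.0149, and 0.00243 with the replicate block). With an estimated correlation, which has little power on 2 residual degrees of freedom, the call was lost (adjusted p = 0.624 in limma camera). It was also lost without mock replicate 1, where the mean was -0.0884. The value rested on SAUR10 and HAT2, since 5 members lay above 0 and the mean of the other 8 was -0.03. Of the 10 named members, SAUR10 fell in the paired fit and 9 did not pass. HAT2, an auxin-induced homeodomain-leucine zipper gene, changed by -0.64 (adjusted p = 0.056 over all probe sets and 0.000993 adjusted over the list alone, both in the paired limma model).

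The cytokinin list was higher as a group, with a mean log2 change of 0.86 (limma camera, adjusted p = 0.0149, and 8.77e-05 with the replicate block). However, only 2 of its 25 members had a named probe set. With an estimated correlation, which has little power here, the call was lost (adjusted p = 0.624 in limma camera). It was also lost without mock replicate 2 (mean 0.64) and without GR24 replicate 2 (mean 0.92). RR16 rose, and ARR15, which encodes another type-A response regulator, changed by 0.05 (adjusted p = 0.969 in the paired limma model), so the group value rested on RR16.

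The other 9 lists with at least 2 measured members did not pass, with adjusted p from 0.319 to 0.919 in the unpaired camera test. They covered auxin biosynthesis, carotenoids, flavonoids, gibberellin, photosynthetic shoot markers, root markers, touch and wounding, xenobiotic detoxification and reference genes. Over all lists, 43 different genes had a named probe set. Of these, 0 passed the unpaired and 2 the paired fit over all probe sets. When adjusted over the list alone, 3 passed in the unpaired fit (AT2G18010, HAT2 and RR16) and 8 in the paired fit. The additional genes in the paired fit were the auxin-responsive IAA29 (-0.34), named after its value was seen, YUC2, an auxin biosynthesis gene (-0.54), the detoxification genes GSTU25 (0.53) and UGT73B5 (-0.66), and the touch-responsive factor WRKY53 (0.36). Without single arrays IAA29 ranged from -0.877 without mock replicate 2 to 0.189 without mock replicate 1, and YUC2 was -0.33 without GR24 replicate 2. GSTU25 was -0.0198 without GR24 replicate 2, and without mock replicate 2 UGT73B5 was 0.0589 and WRKY53 was -0.0862, each with its sign changed. All 5 also differed between preparations, with adjusted p between 0.000964 and 0.0311 in the paired limma model. The fits without single arrays had no pairing, so they mix that difference into the change. Within pairs 1 and 2 each gene moved the same way, which is favoured by their choice on the paired p-value. The changes were -0.39 and -0.30 for IAA29, -0.51 and -0.58 for YUC2, and 0.36 and 0.70 for GSTU25. They were -0.46 and -0.85 for UGT73B5 and 0.16 and 0.57 for WRKY53. The 3 lists of strigolactone synthesis, perception and known response genes had no member with a named probe set and are not analysed here.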

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

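Alternatives that combine the replicate block with another choice, other than limma's default prior, were chosen after the data had been seen. Without the block, 0 probe sets passed under every other setting that was tested with all arrays kept, including an adjusted p under 0.1. The unpaired fit recovered 0% of log2 changes of 0.5 or 1 on simulated data, so these counts of 0 say little about whether GR24 acts. The planned paired fit called 281, and 71 probe sets moved at least 1.5-fold the same way in both pairs, against 8 that moved in opposite ways. Starting from the 69 calls of the paired fit, repeated quantile normalization left 51 and centring on the median 53, all among the 69. Dropping the dimmest probe sets gave 69 calls, 64 of them shared, where 64 of the original calls were still tested. The count changed to 281 with limma's default prior, 261 with trend and robust moderation, 110 at an adjusted p under 0.1, 24 with an offset of 16, 3 with an unmoderated test, and 0 without the block. Tests bearing on the default prior and the block are given with the other observations, and for the other settings the cause was not tested. Without probe sets that differed between preparations it was 41, all among the 42 of the 69 still tested, where only the prior and the adjustment could change. With 1 probe set per gene, which also leaves out every probe set without 1 gene name, it was 17, of the 24 still tested. Repeated quantile normalization kept 17 of the 24 named genes past the threshold, and centring 18. The 2 list shifts held with the block, both scalings, moderation, offset, array weights and averaged probe sets. Dropping the dimmest probe sets left 1, since the cytokinin list then had too few members. An estimated correlation and fry each gave 0, and leaving out single arrays gave 1 to 3. With single arrays left out of the unpaired fit, the lone array being assumed to vary like the other group, genes that did not pass changed sign. Such a fit mixes the difference between preparations into the change. IAA29 lay between -0.877 and 0.189, ARR15 between -0.0193 and 0.122, WRKY53 between -0.0862 and 0.812, GSTU25 between -0.0198 and 1.08 and UGT73B5 between -1.37 and 0.0589. A further 29 list members named by the rule lay between -0.27 and 0.35 and passed under none of 11 settings. Of these, 23 changed sign with some array left out and 2 under some other setting. The level of MAX3 was not run. No detection calls were used here, so the dimmest probe sets have no stated background.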

Other observations

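The tests of preparation difference, prior variance and seedling state were chosen after the results they measure had been seen, as were the comparisons between preparations, of plastid genes and of gene families.

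More probe sets differed between preparations, that is between replicate numbers, than between treatments. With treatment as a block and the likelihood prior, 1851 probe sets were higher and 1954 lower in preparation 2 than in preparation 1. Named genes with large differences, chosen after their values were seen, included AT4G27654 (log2 difference 1.61 ± 0.16, SE, n = 2 pairs), AT2G43620 (1.54 ± 0.12), the Hsp70 nucleotide exchange factor Fes1A (1.29 ± 0.10), the DnaJ gene AT1G71000 (1.35 ± 0.11) and the FKBP-type isomerase gene AT5G48570 (1.28 ± 0.11), all higher in preparation 2. The 1 measured member of the heat shock protein list, ATHSP22.0, was lower (-0.44 ± 0.10, adjusted p = 0.022). AT3G15440 (-1.99 ± 0.12) and AT1G19530 (-1.77 ± 0.11) were lower too. Of the fixed lists, xenobiotic detoxification was higher in preparation 2 (4 genes, mean 0.77, adjusted p = 3.22e-05 in limma camera), as were root markers (3 genes, mean 0.45, adjusted p = 0.0106) and flavonoid genes (2 genes, mean 0.64, adjusted p = 0.0301). All 3 were lost with an estimated correlation (adjusted p = 0.707 each in limma camera). That test has 1 residual degree of freedom here and can hardly call any list, so the loss decides nothing.

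Of the 69 measured plastid-encoded genes, 48 had GR24 minus mock differences of opposite sign in the pairs, 17 were below 0 in both and 4 above 0 in both. Their median difference was 0.17 in replicate 1 and -0.27 in replicate 2, and no single gene passed the paired test. As a group they had a median of -0.06 in the paired design (limma camera, p over all 69 plastid genes = 0.00609, and p = 0.676 with an estimated correlation). The latter test has 1 residual degree of freedom in this design and can hardly call any group. Among 49 gene families defined by a shared symbol, 4 passed limma camera in the paired design, with limma's default prior. They were the response regulators RR (5 genes, mean 0.37, adjusted p = 0.0428), BZIP factors (14 genes, mean -0.12, adjusted p = 0.0428, and higher in preparation 2 by 0.15, adjusted p = 0.0481), genes named RPL (7 genes, mean -0.21, adjusted p = 0.0428) and genes named NAD (8 genes, mean -0.13, adjusted p = 0.0492). None held with an estimated correlation (adjusted p = 0.948 in limma camera), which for the same reason decides nothing. The RR value rested on RR16, as the other 4 had a mean of 0.05. The 7 RPL genes were all plastid-encoded, and 6 of them had opposite signs in the pairs.

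GR24 calls appeared in the paired fit and not in the unpaired fit. With the treatment labels of preparation 2 exchanged, the paired fit with the likelihood prior called 0 probe sets in limma's model, against 69 with the real labels. An unadjusted p under 0.05 was found for 580, against 1700 with the real labels. Only 2 labellings part both pairs, too few for a share under 0.05, and the exchanged contrast is the residual of the real fit. The difference between preparations may account for the empty unpaired fit, since the median residual SD was 1.77 times as large without the block. Part of that ratio arises from the degrees of freedom alone, as a median SD is lower on 1 than on 2. A misjudged prior variance may add to the larger planned count of 281. Of residual variances, 1.56% lay above the 99% point of limma's default prior, where 1% belong, against 0.844% for the likelihood prior. The likelihood prior was fitted to these same variances, so its share is no independent check.

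Called probe sets had neighbours among themselves. There were 3 pairs of probe sets with consecutive numbers that were lower with GR24, 259331_at and 259785_at among their members. The mean was 0.104 and the highest value 3 in 10000 shuffles of the calls. The pairs were not all separate, as 259784_at paired with both 259783_at and 259785_at. Consecutive numbers often mark nearby genes, as 60.1% of 8302 consecutive named pairs lay within 5 genes of each other. Cross-hybridising probe sets could give such pairs. None of the members is marked as shared between genes, so the count without marked probe sets, again 3, decides nothing. Related transcripts and separate neighbouring genes cannot be told apart here, because these probe sets have no gene names.

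GR24 calls overlapped with differences between preparations. Of the 36 probe sets that fell, 14 also differed between preparations, and of the 33 that rose 13 did, against 16.7% of the probe sets not called. Both contrasts share 1 residual variance, so an overlap above that share can arise from it. A seedling state that varied with handling or growth might place the fallen probe sets on 1 side of the preparation contrast, and 57.1% of those 14 were higher in preparation 2 (exact 95% interval 28.9% to 82.3%), against 23.1% of the 13 that rose (Fisher's exact test, two-sided, p = 0.12). With so few probe sets this explanation and the treatment cannot be told apart for them.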
